A study of Mus musculus with 4 samples.

How the data were processed

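The study pulled down RNA bound to a transfected, biotin-tagged microRNA mimic and sequenced it. The cells were fibro-adipogenic progenitors (FAPs), the mesenchymal stromal cells of skeletal muscle, sorted as Sca1-positive cells from wild-type C57Bl/6 mice. They were grown to about 80% confluency, transfected with either a miR-206 mimic or a control mimic for 24 hours, and then kept for 48 hours in a basal medium with 10% horse serum. miR-206 is a microRNA of skeletal muscle. Each mimic was captured in 2 replicate samples, so 4 libraries were compared. Nothing in the labels says whether the replicates came from separate mice, sorts or cultures, so p-values measure only the spread between these samples, which may be technical. No library of unselected RNA is among the 4 samples, so a level in a pulldown was not corrected for the level of the transcript in the cells. The sequence of the control mimic is not given in the sources used here. Libraries were made with SMARTer and NuGEN Ovation kits, per the labels' protocols, which also state that ERCC spike-ins were added and not used to normalise.

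The submitters' processing notes name FastQC, kallisto and the mm10 build. The versions, the transcript annotation and the way transcript values were joined to genes are not given in the sources used here. The deposited table lists 28649 gene rows, each with 1 transcript identifier, an estimated count and a TPM value in each library. The estimated counts were made by the authors with kallisto, per the submitters' processing notes, and they are not all whole, since kallisto divides reads between transcripts that share sequence. Levels of genes with near-identical copies, such as ribosomal protein genes and histones, therefore depend on that division. The TPM values were computed by the authors, per the file headers, and sum to 743941 and 729176 in the control libraries and to 665223 and 629789 in the miR-206 libraries, so 25.6%, 27.1%, 33.5% and 37.0% of the TPM total lie in features not analysed here. The table names 0 ERCC rows and 0 mitochondrially encoded genes. A further deposited sheet keeps the 14870 genes whose mean TPM reached 1 in at least 1 group, and the authors give there each group's mean TPM signal and the log2 of it. Per the file headers these columns are called Ln2 and CPM, but the values are log2 of TPM. A group mean below 1 was set to 0 by the authors, for 422 control means and 2943 miR-206 means, and the log2 value was then 0 or left empty. The deposited log2 fold change is the difference of those 2 log2 values, computed by the authors without a test. A last deposited sheet lists 1675 names of transcription factors, with no other value used here (unit: other, gene names). In 27 rows the gene name had turned into a calendar date. Those rows stayed in the fits and are not named. Columns were tied to samples through the barcodes in the sample titles, and 0 per-sample columns were left without a sample.

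Estimated counts were rounded to whole numbers. The main test was edgeR 4.0.16 (glmQLFit and glmQLFTest with robust estimation, R 4.3.3) with TMM scaling and group as the only term, on the 15240 genes kept by filterByExpr. Adjusted p-values are Benjamini-Hochberg values over these genes, with a threshold of 0.05. A transcript whose adjusted p lies under it is called enriched where its log2 fold (miR-206 over control) is positive, and depleted where it is negative. Normalised CPM are CPM computed with the TMM-scaled library size, and group values are means ± SD of 2 libraries. The SE of a log2 fold is an approximation, the size of the fold divided by the square root of its quasi-likelihood F statistic. The 95% intervals are built from that SE. Neither covers the choice of scaling, which can move a fold outside its interval. Gene lists were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over 18 lists, and again with an estimated correlation and with fry. Of 19 lists written in advance, the mitochondrially encoded genes had no row. Lists were fixed before the data were examined, as were the rule for named genes and most of the alternative settings. That rule takes the 12 enriched and 12 depleted genes with the largest fold among those past the threshold, with a mean of at least 10 normalised CPM and with groups that do not overlap. It adds up to 4 members of each list with the smallest p and at least 1 CPM, Runx1, and the 6 transcription factors with the largest deposited fold. Of the genes so taken or added later, 4 are not reported here. Other genes named in the text were chosen after their values were seen; these are further called members of a list, members of groups tested later and the most abundant transcripts.

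Totals were 8883200 and 14261600 estimated counts in the control libraries and 14566600 and 15426700 in the miR-206 libraries. A floor of 3 counts corresponds to 0.209, 0.157, 0.330 and 0.264 normalised CPM in control replicates 1 and 2 and miR-206 replicates 1 and 2. Reads carry no molecular identifiers here, so floors and counting intervals cover counting error only. The replicates of each group were not duplicates: their counts differed by 47.7 (control) and 61.2 (miR-206) times the sampling variance, as chi-square per degree of freedom. Data were simulated for 15240 genes with the dispersions and library sizes of this comparison and means pooled over both groups. As many genes were raised as lowered. The edgeR fit recovered 7 of 67 genes changed 2-fold, 42 of 67 changed 4-fold and 61 of 66 changed 16-fold, and 16 of its 126 calls were unchanged genes. The real comparison had far more calls, mostly enriched. These rates may therefore not carry over to it, and the simulation did not test the scaling.

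The same replicate numbers occur in both groups and were not taken to pair the samples. Alternatives were RLE and upper-quartile scaling, other count filters, a replicate block, DESeq2 1.42.0, limma-voom, edgeR without robust estimation, a test against a 1.5-fold change, limma on the deposited TPM, and leaving out each library. Planned tests of miR-206 seed sites in 3′ UTRs were not run, since no transcript sequences were used here, nor was scaling on ERCC rows. Gene positions come from the RefSeq annotation of GRCm38.p6, the assembly that mm10 denotes, matched by symbol. Of the 15240 tested genes, 14318 matched a current RefSeq symbol. Symbols are those of the deposited table.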

Results

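RNA captured with a miR-206 mimic was compared with RNA captured with a control mimic in muscle FAPs, 2 libraries each, to find the transcripts that miR-206 binds. The libraries held 8883200 and 14261600 estimated counts (control) and 14566600 and 15426700 (miR-206), and the largest share of any single gene differed between the groups. Bgn, which encodes the matrix proteoglycan biglycan, held 13.9% and 11.8% of the counts in the miR-206 libraries, against 0.960% and 1.12% in the control libraries. Rpl29, a ribosomal protein gene, held 3.52% and 2.62% against 0.108% and 0.121%, Sfrp1, a secreted Wnt antagonist, 2.51% and 1.94% against 0.0422% and 0.0591%, and Lrrc32, which binds latent TGF-beta at the cell surface, 2.00% and 1.55% against 0.0478% and 0.0606%. The control libraries were led by Tmem263, with 1.87% and 2.91% of counts against 0.0142% and 0.0253% in the miR-206 libraries. The 10 most abundant genes together took 28.0% and 25.6% of the miR-206 counts and 13.4% and 15.6% of the control counts. Across 15240 genes, log2 CPM correlated at r = 0.96 between the miR-206 replicates, at r = 0.93 between the control replicates and at r = 0.82 to 0.85 between the groups.

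The first comparison asked which transcripts were more abundant in the miR-206 pulldown. Of the 15240 genes tested, 2327 were enriched and 944 depleted (edgeR quasi-likelihood test, adjusted p under 0.05), and 646 were enriched and 112 depleted at least 8-fold. The groups did not overlap for 62.0% of genes, against a chance share of 33.3% for 2 libraries against 2. The balance of the 2 directions rested on the scaling. With TMM 71.1% of calls were enriched, with the upper quartile 48.8% (1870 enriched and 1962 depleted), with total counts alone 13.4% (1070 and 6909), and with the deposited TPM 15.7% (1093 and 5860). The median log2 fold of all genes moved from -0.11 with TMM to -0.40, -1.22 and -0.70 in these settings. A smaller set was called in the same direction under TMM, RLE, upper quartile, total counts, TPM and median-centred TPM alike, with 966 genes enriched and 655 depleted.

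**Figure D1:**
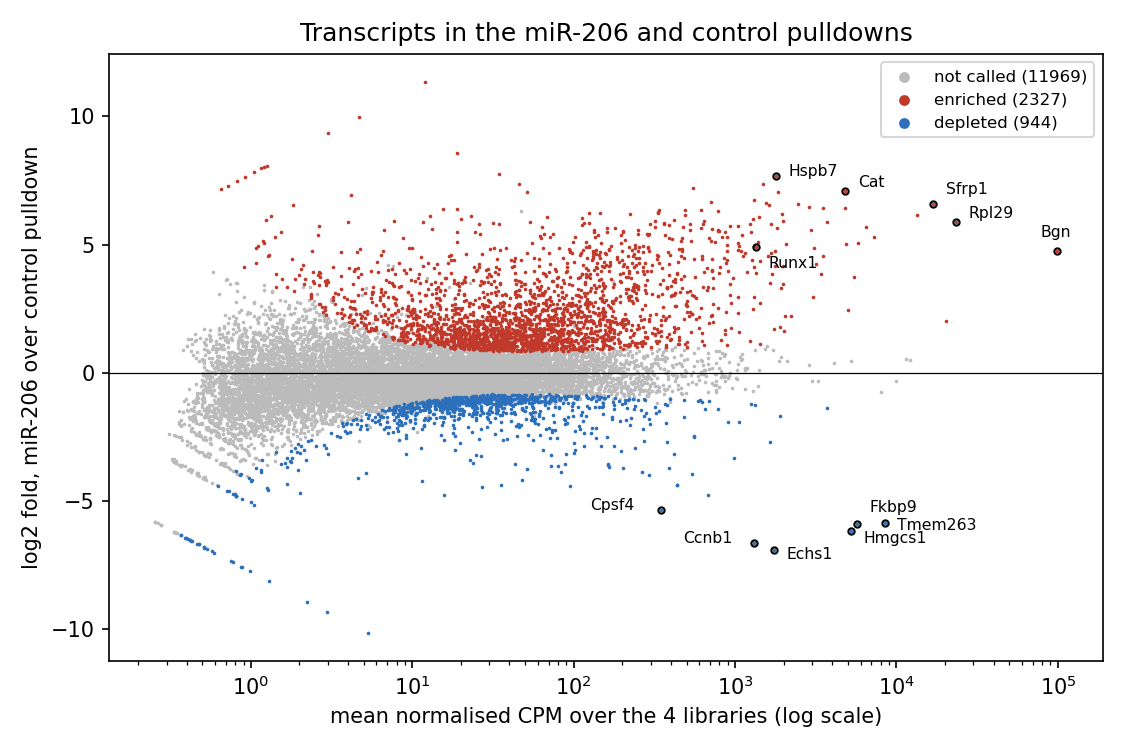
Each point is 1 of 15240 genes, with the mean normalised CPM of the 4 libraries on a log axis and the fitted log2 fold of the miR-206 over the control pulldown on the vertical axis. Red marks the 2327 enriched and blue the 944 depleted genes, and circled genes are named; Bgn, Rpl29 and Sfrp1 lie at the upper right, and Tmem263, Fkbp9, Hmgcs1, Echs1, Ccnb1 and Cpsf4 lie at the lower right, apart from most depleted genes.

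Runx1, a transcription factor of the RUNX family, was higher in the miR-206 pulldown. It was chosen by name before the data were examined, because the published study had reported it as a miR-206 target in FAPs. Its enrichment here is therefore not independent evidence. The gene lies on chromosome 16 from 92601466 to 92826074 (GRCm38). Its level was 2600.2 ± 836 normalised CPM in the miR-206 libraries and 86.8 ± 6.28 in the control libraries (SD, n = 2), a log2 fold of 4.90 ± 0.45 (SE) with a 95% interval from 3.95 to 5.86 (edgeR adjusted p = 3.4e-07). The log2 fold stayed past the threshold in 15 alternatives, at 3.80 or more, with adjusted p between 4.5e-54 and 0.00019.

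The transcripts with the largest enrichment included several enzymes. Hspb7, a small heat shock protein gene (chromosome 4, 141420779 to 141425310), rose from 17.4 ± 1.07 to 3576 ± 693 normalised CPM, a log2 fold of 7.68 ± 0.51 (SE; edgeR adjusted p = 8.3e-08). Mocs1, needed for molybdenum cofactor synthesis (chromosome 17, 49428350 to 49455435), rose with a log2 fold of 7.38 ± 0.52, and Cat, the gene of the peroxide-degrading enzyme catalase (chromosome 2, 103453904 to 103485153), with 7.07 ± 0.56, reaching 9547 ± 3940 CPM from 70.9 ± 6.30. P4ha3, a prolyl 4-hydroxylase subunit that acts on collagen, had a log2 fold of 7.04 ± 0.53, Man1c1, a Golgi mannosidase, 6.74 ± 0.49, and Dnaaf5, a dynein assembly factor, 7.20 ± 0.47. The transcription factor gene Lhx6 (7.06 ± 0.89), the actin-binding coronin gene Coro6 (7.35 ± 0.53) and Samd5 (7.76 ± 0.53) were in the same set. These folds rest on few control counts, with 21 and 3 for Lhx6, 11 and 7 for Coro6 and 7 and 3 for Samd5. The log2 fold of Lhx6 was 9.25 without control replicate 1. Rspo1, a secreted Wnt agonist, had 748 counts over both miR-206 libraries and 3 over both control libraries, a ratio of 408 with an exact counting interval from 139 to 1981. Tmem214 had 0 counts in the control libraries and 50 and 486 in the miR-206 libraries. Its miR-206 mean was 132-fold above a floor of 3 counts per library. Its miR-206 libraries differed widely (5.50 and 42.8 CPM, mean 24.1 ± 26.4), so that ratio rests mostly on replicate 2 and is lower for replicate 1. Its call (edgeR adjusted p = 0.0375) was lost with RLE (0.0527) and without control replicate 1 (0.214) or 2 (0.172).

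The depleted transcripts included some of the most abundant ones of the control pulldown. Echs1, a mitochondrial enoyl-CoA hydratase (chromosome 7, 140105710 to 140116421), fell from 3470 ± 2076 to 28.8 ± 2.79 normalised CPM, a log2 fold of -6.91 ± 0.56 (edgeR adjusted p = 1.5e-07). Ccnb1, encoding cyclin B1 (chromosome 13, 100778739 to 100786486), fell by 6.64 on the log2 scale. Hmgcs1, a cholesterol synthesis enzyme, fell by 6.15, Fkbp9, a peptidyl-prolyl isomerase of the endoplasmic reticulum, by 5.90, and Tmem263 by 5.87, from 16673 ± 7195 to 285 ± 82.2 CPM. Cpsf4, a cleavage and polyadenylation factor, fell by 5.33, and the transcription factor gene Tcf12 by 4.74. Pawr (-4.74 ± 0.48), Echdc3 (-4.43 ± 0.39), Cxcl9, a chemokine (-4.42 ± 0.35), 2510039O18Rik (-4.38 ± 0.39) and Rrad, a small GTPase (-4.37 ± 0.35), completed the 12. The count of depleted genes depended on single libraries: it was 456 without miR-206 replicate 1 and 1567 without control replicate 1, against 944 with all libraries.

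**Figure D2:**
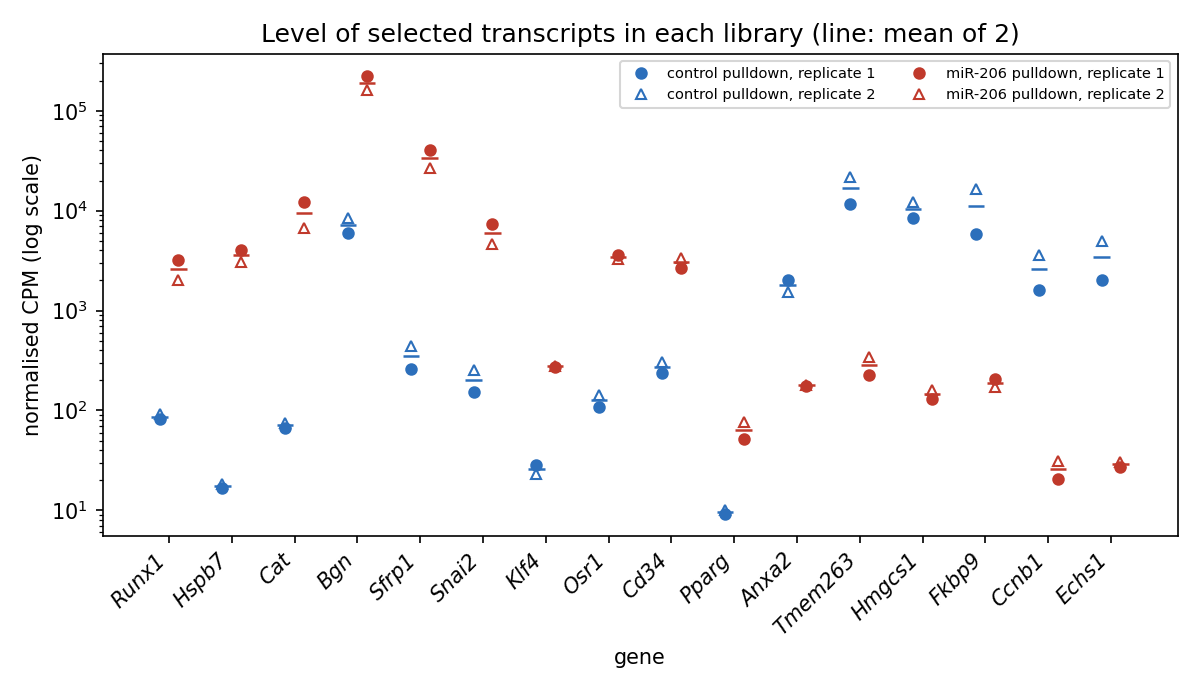
Normalised CPM on a log axis of 16 genes in each of the 4 libraries, with circles for replicate 1, triangles for replicate 2 and a line for the mean of each group. Every miR-206 library lies above every control library from Runx1 to Pparg, and below from Anxa2 to Echs1.

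Published targets of miR-1 and miR-206 were listed in advance, since both microRNAs share a seed. The list includes Runx1, named from the published study, and was not tested without it. Of 35 tested members, 12 were enriched, 6 depleted and 17 did not pass (13 and 6 passed when adjusted over the list alone). Besides Runx1, the enriched members included Snai2, a transcription factor of mesenchymal cells (4.87 ± 0.49), Klf4, a Kruppel-like factor (3.42 ± 0.34), Notch3 (1.92 ± 0.32) and G6pdx, the first enzyme of the pentose phosphate pathway (1.63 ± 0.32). The depleted members were Anxa2 (-3.32 ± 0.40), Tagln2 (-2.68 ± 0.42), Bdnf (-2.42), Cdc42 (-1.90), Met (-1.62) and Tkt (-1.02). As a list no difference from other genes on balance was detected: the mean log2 fold was 0.37 above that of other genes (camera adjusted p = 0.312; adjusted p = 0.859 with an estimated correlation). G6pdx, Notch3 and Met lost their calls under at least 1 of the scalings. Met (adjusted p = 0.0877 and 0.159) and Tkt (0.0769 and 0.0842) also lost theirs without miR-206 replicate 1 or 2 in edgeR.

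RUNX and osteochondrogenic genes were higher as a list with the preset correlation, but not with an estimated correlation or with fry (fry adjusted p = 0.138). The list includes Runx1, named from the published study, and was not tested without it. Of 13 tested members 5 were enriched and 0 depleted (the same numbers adjusted over the list alone), with a mean log2 fold 1.29 above other genes (camera adjusted p = 0.0112; adjusted p = 0.859 with an estimated correlation). The 5 were Runx1, Alpl, the bone-type alkaline phosphatase gene (4.59 ± 0.40), Runx3 (2.86 ± 0.54), the homeobox gene Msx1 (2.31 ± 0.44) and Runx2 (1.19). Alpl rose from 11.5 ± 1.61 to 277 ± 117 CPM, while Runx3 was less abundant, with 16 and 36 control counts and 118 and 103 miR-206 counts. Runx2 and Runx3 lost their calls under at least 1 scaling and without miR-206 replicate 1 (edgeR adjusted p = 0.0701 and 0.0596). Without control replicate 1 the list shift was 0.96 with a camera adjusted p of 0.0783.

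More adipogenesis genes were enriched than depleted, as in all tested genes (15.3% enriched and 6.19% depleted), and they did not pass as a list. Of 35 tested, 8 were enriched and 1 depleted (8 and 1 adjusted over the list alone; camera adjusted p = 0.0719, mean shift 0.66). Bmp4, a growth factor that commits progenitors to fat (5.42 ± 0.44), its receptor Bmpr1a (3.22 ± 0.38), Pparg, the master regulator of fat cell differentiation (2.73 ± 0.32), and the fatty acid desaturase gene Scd1 (2.36 ± 0.39) were enriched, as were Cebpa (2.14) and Srebf1 (1.56). The depleted member was Lpl, lipoprotein lipase (-1.37 ± 0.40). Srebf1 lost its call under at least 1 scaling, and Lpl without control replicate 2 or miR-206 replicate 1 (edgeR adjusted p = 0.120 and 0.0630). The list passed under 4 of its 11 alternatives: no count filter (camera adjusted p = 0.00294), the replicate block (0.035), and without control replicate 2 (0.0443) or miR-206 replicate 2 (0.0191), but it had an adjusted p = 0.859 with an estimated correlation.

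Genes of FAP and fibroblast identity and of TGF-beta and BMP signalling also held more enriched than depleted members. The same holds for all tested genes (15.3% enriched and 6.19% depleted), so that excess alone does not set these lists apart. In the FAP list 7 of 23 were enriched and 1 depleted (7 and 2 adjusted over the list alone; camera adjusted p = 0.0885), with Osr1, a transcription factor of FAPs (4.76 ± 0.44), the progenitor surface genes Cd34 (3.49 ± 0.42) and Thy1 (2.92 ± 0.39), and Hic1, a marker of quiescent mesenchymal progenitors (2.22 ± 0.33). In the TGF-beta and BMP list 8 of 30 were enriched and 2 depleted (10 and 2 adjusted over the list alone; camera adjusted p = 0.0885), with the receptor genes Tgfbr2 (3.53 ± 0.40), Bmpr2 (3.25 ± 0.37) and Bmpr1a, and Ski, an inhibitor of SMAD signalling (3.74 ± 0.40). The depleted members were the BMP-responsive genes Id2 (-1.04) and Id3 (-1.03), whose calls were lost without control replicate 2 (edgeR adjusted p = 0.169 and 0.211; log2 fold of Id2 -0.66) or miR-206 replicate 1 (0.259 and 0.235). Both lists passed without the count filter (camera adjusted p = 0.00606 for each) and without miR-206 replicate 1 (0.0365 for each), and the TGF-beta and BMP list without control replicate 2 (0.0325), all with the preset correlation. Without control replicate 1 the mean log2 fold above other genes fell from 0.60 to 0.37 for the FAP list (adjusted p = 0.464) and from 0.56 to 0.21 for the TGF-beta and BMP list (0.611). With an estimated correlation in the fit on all libraries, the adjusted p was 0.859 for each.

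Extracellular matrix genes split, with 7 of 35 enriched and 4 depleted (8 and 4 adjusted over the list alone; camera adjusted p = 0.945). Bgn rose by 4.74 ± 0.59 on the log2 scale, reaching 191363 ± 44925 CPM, and Fn1, fibronectin, by 1.76 ± 0.38 and Col4a1 by 1.21 ± 0.34, while Col6a3 (-2.66 ± 0.42) and Col1a2 (-1.27) fell. Fn1 and Col4a1 lost their calls under at least 1 scaling. Calls were also lost for Col4a1 and Col1a2 without control replicate 2 (edgeR adjusted p = 0.0985 and 0.143), Col4a1 without miR-206 replicate 1 (0.0596) and for Col1a2 without miR-206 replicate 2 (0.0690). The mean of this list lay 0.03 above other genes, while camera gave a downward direction. Actin and adhesion genes had 10 of 40 enriched and 3 depleted (12 and 4 adjusted over the list alone; camera adjusted p = 0.382), among them Pfn1, profilin (3.31 ± 0.45), and Tpm4, a tropomyosin (2.97 ± 0.46), which rose, and Tagln2 and Cdc42, which fell.

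Cell cycle genes went both ways, with 6 of 33 enriched and 5 depleted (6 and 5 adjusted over the list alone; camera adjusted p = 0.382). Ccnb1 and Mcm2, a replication licensing gene (-2.64 ± 0.40), fell, and Ccnd3 (3.30 ± 0.40) and Ccna2 (1.71 ± 0.30), both cyclin genes, rose. In the pentose phosphate and glycolysis list 5 of 23 were enriched and 1 depleted (camera adjusted p = 0.593; 5 and 1 adjusted over the list alone), led by Hk1, hexokinase 1 (3.12 ± 0.37), and the glucose transporter gene Slc2a1 (2.10 ± 0.34), with Rpe at 1.47 ± 0.30. Of 18 genes of the microRNA machinery 4 were enriched and 1 depleted (5 and 1 adjusted over the list alone; camera adjusted p = 0.442): Ago2, the Argonaute with slicer activity (3.38 ± 0.40), Tnrc6c (2.20 ± 0.36), Ago3 (1.34 ± 0.30) and Pan3 (1.25 ± 0.33) rose. Calls of Ccna2, Rpe, Ago3 and Pan3 were lost under at least 1 scaling, that of Ago3 also without miR-206 replicate 1 (edgeR adjusted p = 0.0526) and that of Pan3 without control replicate 2 (0.0651).

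Ribosomal protein transcripts were lower as a list with the preset correlation, but not with an estimated correlation or with fry (fry adjusted p = 0.239). Of 85 tested, 14 were depleted and 4 enriched (13 and 4 adjusted over the list alone). Their mean log2 fold lay 0.48 below other genes (camera adjusted p = 0.00376, and 0.859 with an estimated correlation). Rps7 (-1.95 ± 0.34), Rps15a (-1.74 ± 0.32) and Rps13 (-1.67 ± 0.32) fell, while Rpl29 rose by 5.87 ± 0.57. Many of these genes have near-identical copies, so their counts are uncertain. Without miR-206 replicate 2 the list shift was -0.16 with a camera adjusted p of 0.0671. For interferon and double-stranded RNA response genes no shared shift was detected, with 2 of 25 enriched and 3 depleted (2 and 3 adjusted over the list alone; camera adjusted p = 0.442). Ifi44 (5.56 ± 0.50) and the RNA sensor gene Ddx58 (1.91 ± 0.32) rose, and Stat2 (-1.68 ± 0.37) and Ifi27 (-1.38 ± 0.29) fell. Of 19 histone genes 2 were enriched and 2 depleted (2 and 2 adjusted over the list alone; camera adjusted p = 0.524). Hist1h2ao had 0 control counts and a miR-206 mean 13.7-fold above the floor of 3 counts per library. Hist3h2a had a log2 fold of 1.23 ± 0.33, Hist1h2ap fell by 1.94 and H1f0, with -0.71 ± 0.29, did not pass. Ddx58 and Hist3h2a lost their calls under at least 1 scaling, Hist3h2a also without miR-206 replicate 1 or 2 (edgeR adjusted p = 0.146 and 0.0789), and Hist1h2ap without control replicate 2 (0.0859) or miR-206 replicate 1 (0.0779). The log2 fold of Hist1h2ap was -3.08 without miR-206 replicate 2. H1f0 passed with the upper quartile (0.0151), with TPM and with at least 50 counts (0.0401).

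Markers of other cell types that the Sca1 sort could hold moved in both directions. Of 13 endothelial markers 3 were enriched and 1 depleted (4 and 2 adjusted over the list alone, camera adjusted p = 0.779). Erg (4.30 ± 0.70), Cdh5 (2.40 ± 0.54) and Eng (1.78 ± 0.33) rose and Egfl7 (-1.79 ± 0.39) fell. Erg and Cdh5 were low, with deposited log2 TPM of 1.41 and 1.37 for miR-206 and 0 for the control. Of 13 pericyte and smooth muscle markers 3 were enriched and 1 depleted (3 and 1 adjusted over the list alone; camera adjusted p = 0.312): Abcc9 (4.92 ± 0.51), Rgs5 (4.63 ± 0.42) and Notch3 rose and Ndufa4l2 (-1.55 ± 0.34) fell. Of 21 myogenic genes 4 were enriched and 1 depleted (4 and 1 adjusted over the list alone, camera adjusted p = 0.917). Myod1, the myogenic determination gene (3.10 ± 0.78, enriched), was low, with 59 and 11 control counts and 225 and 167 miR-206 counts. Tnnt1 had a log2 fold of 1.68 ± 0.47, Chrna1 of 1.63 ± 0.37 and Vcam1 of -1.12 ± 0.33. Of 7 Schwann cell and tenocyte markers 3 were enriched and 0 depleted (3 and 0 adjusted over the list alone; camera adjusted p = 0.382): Ngfr (4.77 ± 0.47) and Fmod (1.74 ± 0.55) were among those that rose, and Mkx, with -0.86 ± 0.39, did not pass, though it did without control replicate 2 (-1.23, adjusted p = 0.0174) and with TPM over genes of mean TPM at least 5 (-1.04, 0.0359). Of 8 haematopoietic markers 0 were enriched and 1 depleted (0 and 2 adjusted over the list alone; camera adjusted p = 0.442): C1qa had 115 control counts and 3 miR-206 counts, a ratio of 0.0427 with an exact counting interval from 0.00867 to 0.128, while Csf1r (-0.92 ± 0.55), Ms4a1 (0.48 ± 0.46) and Cd68 (0.49 ± 0.72) did not pass. With TPM, Csf1r passed as depleted at pseudocount 1 (-0.94, adjusted p = 0.0490), and Cd68 turned and passed as depleted at pseudocounts 1 and 0.1 (-0.98 and -1.19, adjusted p = 0.0365 and 0.0364). Calls of Cdh5, Eng, Myod1, Notch3, Tnnt1, Chrna1, Vcam1, Fmod and C1qa were lost under at least 1 scaling. In edgeR fits without 1 library, calls were lost for Tnnt1, Chrna1, Vcam1 and Fmod without miR-206 replicate 1 (adjusted p = 0.560, 0.0702, 0.240 and 0.351), for Cdh5, C1qa and Fmod without miR-206 replicate 2 (0.225, 0.0953 and 0.160), for Tnnt1, Vcam1 and C1qa without control replicate 2 (0.312, 0.0704 and 0.227) and for Tnnt1 without control replicate 1 (0.175). Log2 folds moved by over 1 for Myod1 (5.07) and Erg (5.70) without control replicate 1, for Abcc9 (5.96) and C1qa (-3.13) without control replicate 2 and for Tnnt1 (0.64) without miR-206 replicate 1.

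**Figure D3:**
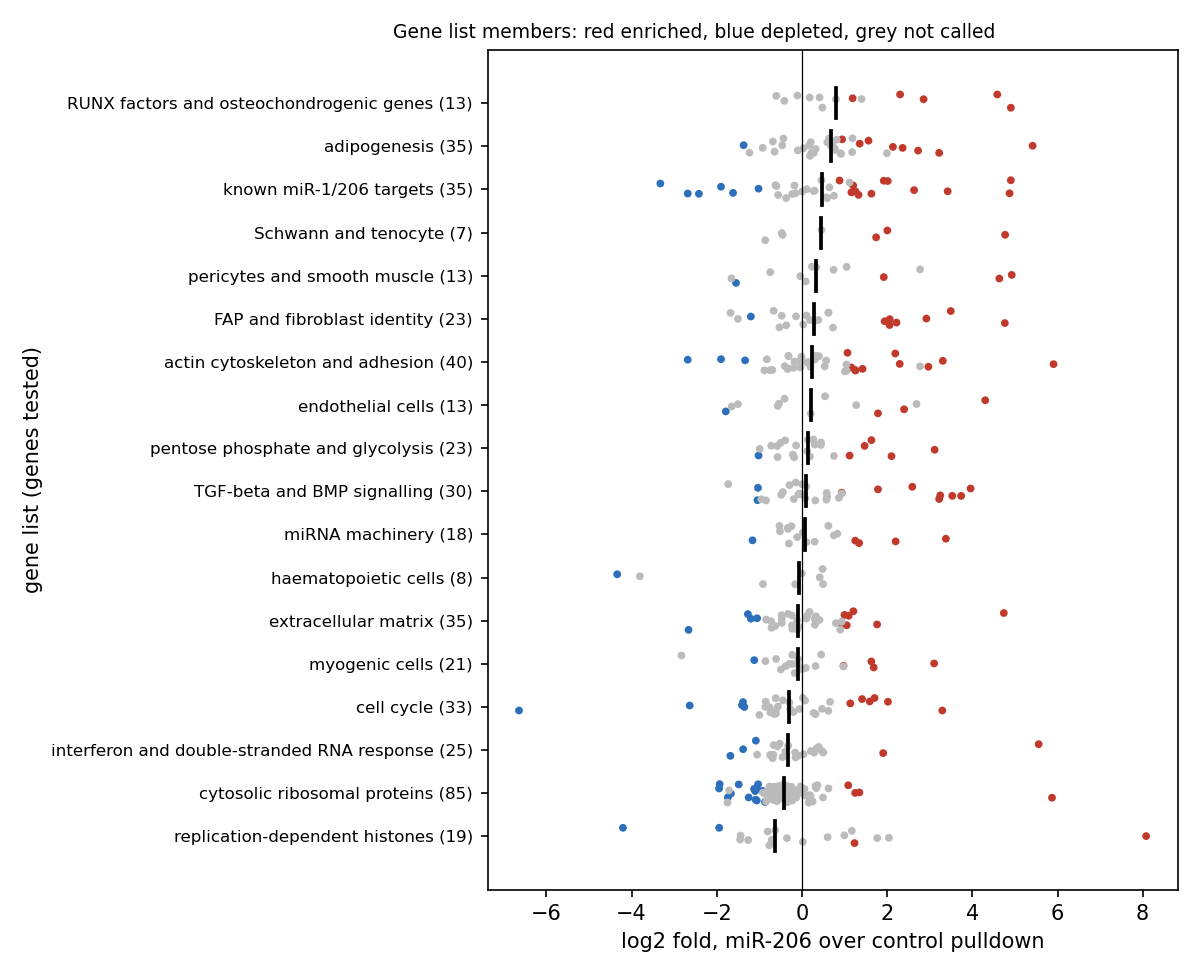
Fitted log2 fold (horizontal axis) of every tested member of the 18 gene lists, ordered by the list median (black bar), with enriched members in red, depleted members in blue and others in grey. RUNX and osteochondrogenic genes have the highest median and histones the lowest, while lists such as cell cycle and extracellular matrix hold members at both ends.

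A further comparison took the transcription factors, which the study listed apart. Among 972 tested genes on the deposited list of transcription factors, 188 were enriched and 51 depleted (192 and 57 adjusted over the list alone), a share of 19.3% enriched against 15.3% of all tested genes. No difference of the list from other genes on balance was detected (camera p = 0.129; p = 0.381 with an estimated correlation). In the authors' deposited table, large log2 folds among transcription factors included those of Nab2 (5.52), Nudt12 (5.27), Ebf3 (4.87), Nab1 (4.71) and Sirt6 (4.62). In the edgeR fit these genes had log2 folds of 6.44 ± 0.53, 5.82 ± 0.42, 5.80 ± 0.48, 5.65 ± 0.47 and 5.56 ± 0.45. Nab1 and Nab2 encode corepressors of early growth response factors, Ebf3 an early B cell factor family member and Sirt6 a chromatin deacetylase. The 905 listed factors found in the deposited fold table were ordered here by their deposited log2 fold. Runx1 ranked 16 among them, with a deposited log2 fold of 3.88, and Snai2 had 3.94. The 20 factors that the authors set apart were chosen on these samples, and their enrichment is therefore not independent evidence.

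The deposited folds were lower than those of the edgeR fit, by a median of 0.93 on the log2 scale over 13672 genes, and correlated with them at r = 0.89 across genes, which are not independent replicates. The log2 fold was at least 1 for 1200 genes and -1 or less for 6735 genes in the authors' deposited table. Of the 2298 edgeR-enriched genes found in the authors' deposited table, 2124 had a deposited fold above 0, and of the 932 depleted genes 931 had a deposited fold below 0.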

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

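Alternatives added after seeing the data were total counts alone, leaving out the 20 most abundant genes, thinning, the length trend and centred TPM. Enriched genes numbered 1093, 1102 and 1002 with the deposited TPM (pseudocount 1, pseudocount 0.1, mean TPM of at least 5) and 1070 with total counts alone, against 2327 in the fit reported, and 1721 to 2533 when 1 library was left out. Depleted genes, 944 in that fit, numbered 5860, 5842 and 4574 with the same TPM settings, 6909 with total counts alone, 1962 with the upper quartile, 388 against a 1.5-fold change, 1616 with the length trend removed without keeping the median, and 456 to 1567 when 1 library was left out. Calls in the other settings, including the replicate block (2576 enriched and 1129 depleted), stayed within 1.5 times. The differences between replicates correlated at -0.08 across genes between the groups. That gives no sign of pairing, but it cannot exclude a shared mouse, sort or culture. The total-count setting differs from the fit reported only in its scaling factors. TPM differs in unit and model too, and although centred TPM gave 2019 and 955, centring itself sets the balance, so the cause of the TPM shift stays open. No call turned into its opposite except 3 genes with TPM at either pseudocount and 8 with the TPM minimum. Leaving out 1 library kept 1491 enriched and 263 depleted genes in all 4 cases. Runx1 kept its direction and its call in all 15 alternatives. Among 115 other genes taken by the naming rule or added later, calls were lost for 21 with TPM at either pseudocount, 12 with the TPM minimum (98 tested), 8 with the upper quartile, 2 without the count filter, 1 each with RLE, limma-voom and no robust estimation, and 19, 10, 4 and 12 without miR-206 replicate 1, miR-206 replicate 2, control replicate 1 and control replicate 2. Calls were gained for H1f0, Mkx, Csf1r and Cd68 (values in the report). Of the 111 called among these genes and Runx1, leaving out 1 library moved the fold by over 1.5 times in 30 and over 2 times in 9. With TPM, Ms4a1, Cd68 and Sufu turned to -0.33, -0.98 and -0.21 (pseudocount 1) and -0.41, -1.19 and -0.24 (pseudocount 0.1), and Sufu also with the TPM minimum (-0.21). For gene lists the value is the mean log2 fold above other genes. Without the count filter, adipogenesis (0.95), FAP identity (0.88), TGF-beta and BMP (0.86) and the transcription factors (0.40) passed the threshold, and the myogenic (0.21) and Schwann and tenocyte (-0.025) lists changed sign. With at least 50 counts, extracellular matrix (-0.14) and myogenic genes (0.10) changed sign. With the replicate block, adipogenesis passed (0.69) and myogenic genes changed sign (0.0050), and the block changed no call of another list or of these genes. These list calls use the preset correlation; with an estimated correlation in the fit reported, p was 0.381 for the transcription factors and adjusted p 0.859 for adipogenesis, FAP identity and TGF-beta and BMP. With an estimated correlation and with fry, the RUNX (1.29) and ribosomal (-0.48) lists no longer passed. The test fry asks whether a list differs from no change, not from other genes, and it passed the transcription factors (mean 0.25 above other genes). Leaving out 1 library gave 0.24 to 1.03 for adipogenesis, 0.96 to 1.56 for RUNX, 0.37 to 0.73 for FAP identity, 0.21 to 0.81 for TGF-beta and BMP, 0.18 to 0.58 for published targets, 0.20 to 0.58 for actin and adhesion, 0.16 to 0.53 for miRNA machinery, -0.68 to -0.16 for the cell cycle, -1.18 to -0.44 for haematopoietic markers, -0.77 to -0.16 for ribosomal proteins, and ranges crossing 0 for extracellular matrix (-0.26 to 0.20), pentose phosphate (-0.086 to 0.34), myogenic (-0.59 to 0.45), endothelial (-0.048 to 0.61), interferon (-0.39 to 0.020) and histone genes (-0.22 to 0.16). The cause was not tested unless stated. Seed-site and ERCC alternatives were not run. With 1 library left in a group, that library is assumed to vary like the other group.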

Other observations

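All tests in this part were chosen after the results of the report were seen, and those of capture by the control mimic, of the choice of scaling and of the length trend with the median kept or absent after the deciding values too. Hedgehog pathway genes other than Smo, the receptor that prompted the question, were tested as a group. Of 15 genes 5 were enriched and 0 depleted, with a median log2 fold of 0.62, and the enriched genes included Evc (2.49 ± 0.30), Disp1 (1.29 ± 0.40), Gli2, a transcription factor of the pathway (1.29 ± 0.43), and Sufu (0.91 ± 0.31). Calls of Disp1, Gli2 and Sufu were lost under at least 1 scaling and without miR-206 replicate 1 (edgeR adjusted p = 0.208, 0.153 and 0.229) or 2 (0.0624, 0.393 and 0.203), and those of Disp1 and Sufu without control replicate 1 (0.0775 and 0.0635). Without control replicate 2 the log2 fold of Disp1 was 1.95. Whether the group is higher was left open (camera p = 0.0655, 0.197 adjusted over 3 groups; p = 0.188 with an estimated correlation). Of 31 Wnt receptors and secreted modulators other than Sfrp1 and Rspo1, 5 were enriched and 2 depleted, and of 23 sterol synthesis genes other than Hmgcs1 and Fdps 2 were enriched and 1 depleted. Neither group passed camera (p = 0.639 and 0.585, adjusted p = 0.639 for each; p = 0.748 and 0.839 with an estimated correlation).

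The published-target list held more enriched members than the tested genes as a whole (12 of 35, Fisher's exact test, two-sided, adjusted p = 0.038 over 18 lists, a test added after seeing the counts) and 6 depleted ones (adjusted p = 0.173). Of the other lists, ribosomal proteins passed the same Fisher's exact test, with fewer enriched (adjusted p = 0.038) and more depleted members (adjusted p = 0.0123). The deposited transcription factors, tested apart from the 18 lists, held more enriched members too (188 of 972, unadjusted Fisher p = 0.000381; camera p = 0.381 with an estimated correlation). Fisher's exact test treats genes as independent. Camera with an estimated correlation gave adjusted p = 0.859 for the published targets and for the ribosomal proteins. None of these differences is therefore secure. The 12 enriched targets also include Runx1, which was named from the published study. Gene families by symbol root were also compared, 94 of them with at least 15 tested members. None passed after adjustment; the smallest adjusted p were 0.0509 for Rps (1 of 45 enriched and 8 depleted) and 0.0715 for Rgs, regulators of G-protein signalling (6 of 19 enriched and 0 depleted). Pseudogenes were lower as a class (372 tested, median log2 fold -0.72, camera adjusted p = 0.00385 over 4 RefSeq classes, with the preset correlation alone), with the caveat that their reads are shared with parent genes.

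Longer transcripts were enriched more often. In 5 equal groups by effective length, derived from the ratio of count to TPM, 7.61%, 12.2%, 15.3%, 18.0% and 23.1% of genes were enriched from the shortest to the longest, and 8.56%, 6.79%, 6.14%, 5.15% and 4.33% depleted (Spearman rho of length with log2 fold 0.20 across genes). Ribosomal protein transcripts are short, at a median of 0.262 times the typical effective length, so length was tested as the whole cause of their lower mean. Their mean log2 fold of -0.38 lay at percentile 0.34 of 10000 lists matched on length and expression, whose central 95% ran from -0.29 to 0.25. The mean was thus below that of most matched lists. These lists ignore the correlation among ribosomal protein genes, estimated at 0.609, so their range is too narrow to decide on length. A shift shared by a few libraries stays open too, as does a biological difference between the mimics.

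More genes were enriched than depleted, 71.1% of calls. Thinning all libraries to the depth of control replicate 1, with TMM fitted again, kept that share at 70.4%. Unequal total counts were therefore not needed for the share under that scaling. Thinning equalised total counts and not the TMM-scaled library sizes, so depth after scaling was not tested. Leaving out the 20 most abundant genes with RLE scaling gave 72.2%, against 72.0% with RLE on all genes. RLE scaling hardly depends on so few genes, so a few dominant genes stay open as an explanation. Removing the length trend gave 54.4%, which met the prediction for length as the cause, written before that value was seen. That version also lowered the median fold by 0.19 on the log2 scale. Lowering all folds by that amount with no length trend gave 56.2%. A version that kept the median fold, added after this, gave 68.3%. Each version sets the median fold, on which the balance depends, so neither decides and length stays open. With total counts alone the share was 13.4%. That setting moves the folds together, to a median log2 fold of -1.22, so a lower share was fixed in advance. It shows that the balance depends on the scaling, but not which scaling is right. Without spike-in counts or input RNA the true balance cannot be set. Capture of many miR-206 targets remains an open biological explanation.

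A small set of transcripts was far higher in the control pulldown. The 112 genes depleted at least 8-fold held 8.54% of control counts and 0.109% of miR-206 counts. The smallest of the 4 control over miR-206 ratios had a median of 5.99, and was at least 4 in 77 of the 112. These genes were chosen by fold and adjusted p on the same libraries, which favours a large smallest ratio. The median is therefore not independent evidence. In those 77 genes the difference was present between every control and every miR-206 library, so no single library carried it. For the rest of the 112 this stays open. The 112 genes were 17.7 times as frequent among the 100 most abundant control transcripts as among tested genes (13 of 112). Genes enriched at least 8-fold were likewise 16 times as frequent among the 100 most abundant miR-206 transcripts (68 of 646). Choosing genes by a large fold favours high levels in the group where they are higher, so neither ratio decides between explanations. One untested hypothesis is that the control mimic captured these transcripts, in which case Tmem263, Fkbp9, Hmgcs1, Echs1 and Ccnb1 may be its own targets. Lowering by miR-206 in the cells cannot be told apart from this, since no input library was compared and the control sequence is not given in the sources used here.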
